A study of Schizosaccharomyces pombe with 5 samples.

How the data were processed

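RNA of Schizosaccharomyces pombe was measured on 5 spotted oligonucleotide arrays, each hybridised with cDNA in Cy5 and cDNA in Cy3. Per the labels, cells grew at 30 degrees, about 30 ug of total RNA was reverse transcribed with aminoallyl-dUTP, and about 1.5 ug of cDNA was coupled to each dye. Per the labels, Cy5 carried wild-type cDNA on 2 arrays and tra1-1 cDNA on 3 arrays, and Cy3 carried wild-type cDNA on all 5, with no dye swap.

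The deposited values are log ratios of the 2 channels, 1 per probe and array, in a table of 9858 probes, and they were taken as log2. The log base, the channel in the numerator, the scanner, any background correction and any normalization within arrays are not given in the sources used here. The direction Cy5 over Cy3 is therefore likely and not certain, on the basis that the labels place each sample in the first channel. All pairs of arrays correlated above 0, with a lowest r of 0.40 over genes, so the columns run the same way. The deposited column medians were -0.23 and -0.39 for the arrays labelled wild type 1 and 2, and -0.43, -0.21 and -0.43 for the arrays labelled tra1-1 replicates 1, 2 and 3, so the columns had not been centred on their medians. Loess normalization, signal over background and spot flags need channel intensities, which were not analysed here.

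Each array was centred on its median. Probes were named through the platform annotation, in which 9632 probes had 1 gene symbol and 44 had several, and 182 probes were not listed and stay unnamed. Of the 4816 named genes, 4804 symbols matched the gene table of the reference assembly ASM294v3, which served only for names and for gene order, because no genome build is named for the array. Each gene had 2 oligonucleotides, and their mean was used, or the remaining value where 1 of them had none on an array. For 4673 genes both had a value on every array. Of 4929 genes and unnamed probe pairs, 22 lacked a value on at least 1 array and were left out, which left 4907, of which 4795 were named. Probes without a value numbered 163, 120, 32, 26 and 57 in the same order of arrays. The number of arrays limits the precision. The median standard error of a group difference was 0.18 on the log2 scale.

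Groups, main tests and gene lists were set before the data were examined, as were the alternatives except a few added later, which the closing section names. The main comparison was the difference between the 3 arrays labelled tra1-1 and the 2 labelled wild type, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 5 arrays, 2-sided, with Benjamini-Hochberg adjustment at 0.05. A dye effect common to all arrays cancels in this difference. The ratio on the 2 arrays labelled wild type was tested against 0 in the same fit, and the ratio on the 3 arrays labelled tra1-1 was tested against 0 in a fit of those arrays alone. A difference of at least 1 on the log2 scale (2-fold) with the 3 arrays on the same side of both others was counted without a test.

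Of 31 gene lists, 30 had at least 5 measured members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with the correlation estimated for each list, and with fry. The list of Tf2 retrotransposons had 0 measured members and was not tested, and 1 of the 30 tested lists is counted but not reported here. Older symbols in the lists were updated through the synonyms of the reference table. Each list's genes were also adjusted over the list alone.

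Named genes followed a fixed rule. It took 14 genes of interest whatever their values and, per direction, the 12 genes with the largest difference among those past the test. Where fewer passed, the 12 were filled by the smallest unadjusted p among genes whose 3 arrays labelled tra1-1 lay on the same side of both others. It also took up to 4 members of a list by the smallest p. The genes named for the ratios against 0 were chosen after their values were seen, from those with the largest means among genes past the test.

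The scripts were tested on simulated data for 4907 genes with the spread of the 5 arrays. For the group difference, 20% of 50 genes changed by 0.5 on the log2 scale were recovered. It was 96% for a change of 1 and 100% for 2 or 3, with 4 false calls among 162. With the spread without the array labelled tra1-1 replicate 3, 14 of 189 calls were false. For the ratios labelled tra1-1 and wild type against 0, 23 of 212 and 6 of 181 were false. Simulated noise was independent between genes and arrays, without the split of the arrays labelled tra1-1 described below. The shares recovered therefore do not give the power of the comparison in the data. Alternatives were a replicate block, the values as deposited, quantile and scale normalization, other handling of missing values and probes, a robust prior, array weights and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.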

Results

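Transcript levels of the fission yeast Schizosaccharomyces pombe were compared on 5 spotted oligonucleotide arrays read in 2 colours. Per the labels, 2 arrays held wild-type cDNA in both dyes, a self-self hybridisation by that label. The other 3 arrays held cDNA of the tra1-1 strain in Cy5 and wild-type cDNA in Cy3. tra1 encodes a counterpart of human TRRAP, a large scaffold protein of the SAGA acetyltransferase complex, and its paralog tra2 encodes the scaffold of NuA4. The series title names Wee1, the kinase that delays mitosis by phosphorylating Cdc2. Each array gave a value for 9695 to 9832 of 9858 probes, and 4907 genes were measured on all 5. Values are log ratios, taken as log2 of Cy5 over Cy3, with the median of each array set to 0. The log base and the direction are not stated with the values. The labels call the experiments independent without saying that they came from separate cultures, so p-values measure the spread between these arrays.

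tra1 transcript was low on both arrays labelled wild type and near 0 on the arrays labelled tra1-1 replicates 1 and 2. Its ratio was -1.41 and -2.04 on the arrays labelled wild type 1 and 2. On the arrays labelled tra1-1 replicates 1, 2 and 3 it was 0.04, 0.02 and -2.21. Counted from the lowest of 4907 genes, tra1 ranked 20, 7 and 4 on the arrays labelled wild type 1, wild type 2 and tra1-1 replicate 3, and 2737.5 and 2598 on the arrays labelled tra1-1 replicates 1 and 2. If the deposited ratio were Cy3 over Cy5, the same ranks would count from the highest. Both tra1 oligonucleotides were low on the same arrays, with -1.61 and -1.21 on that labelled wild type 1, -2.66 and -1.42 on that labelled wild type 2, and -2.27 and -2.15 on that labelled tra1-1 replicate 3. They stood at -0.03 and 0.12 on the array labelled tra1-1 replicate 1 and -0.30 and 0.34 on that labelled replicate 2. By its label a self-self array has the same kind of RNA in both dyes, and the tra1 ratio went against that on both such arrays. The labels do not say what the tra1-1 mutation changes in the gene. The groups below keep the deposited labels, and every direction between them carries this doubt.

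**Figure D1:**
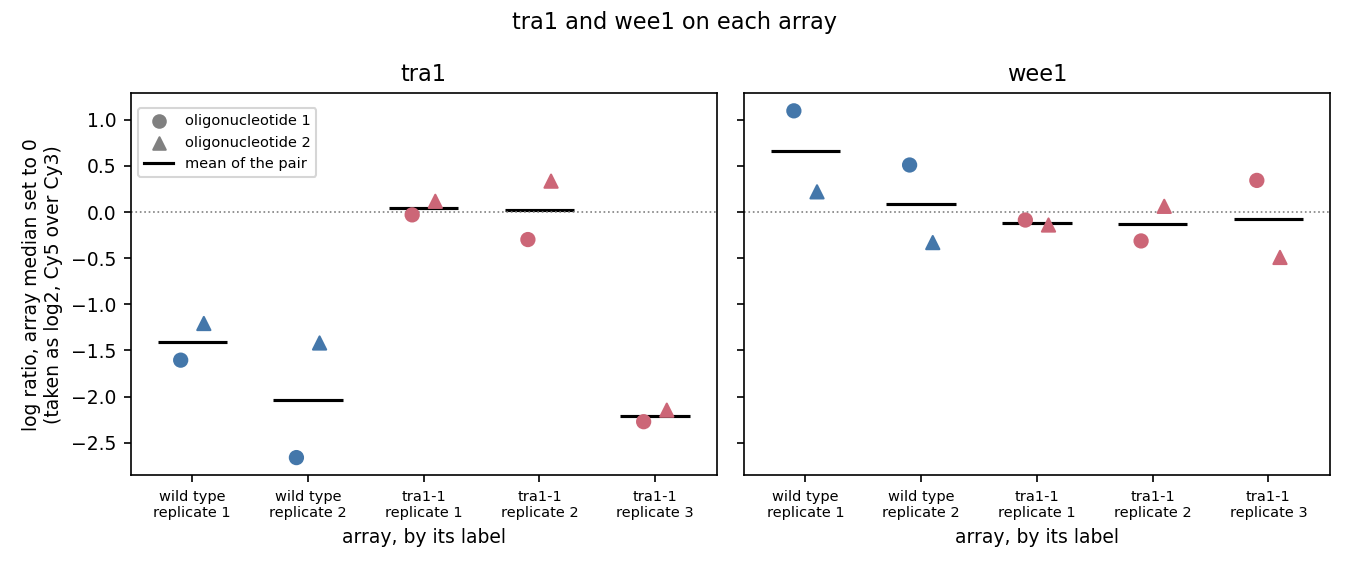
Log ratio (y axis, taken as log2 of Cy5 over Cy3, array median set to 0) of tra1 (left) and wee1 (right) on each of the 5 arrays by its label (x axis); circles and triangles are the 2 oligonucleotides of the gene, bars their mean, blue the arrays labelled wild type and red those labelled tra1-1. The tra1 means were -1.41, -2.04 and -2.21 on the arrays labelled wild type 1, wild type 2 and tra1-1 replicate 3 and 0.04 and 0.02 on the others, while the wee1 means ran from -0.13 to 0.66.

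The arrays split in the same way over the whole genome. Across genes, which are not independent replicates, the ratios on the array labelled tra1-1 replicate 3 correlated with r = 0.72 and 0.74 with the arrays labelled wild type 1 and 2, and with 0.47 and 0.47 with the arrays labelled tra1-1 replicates 1 and 2. The arrays labelled wild type correlated with each other at 0.75. Genes at least 1 from 0 numbered 112, 96 and 168 on the arrays labelled wild type 1, wild type 2 and tra1-1 replicate 3, and 8 and 17 on those labelled tra1-1 replicates 1 and 2. The 2 oligonucleotides of a gene correlated with r = 0.41, 0.40 and 0.38 on the former arrays and 0.13 and 0.12 on the latter.

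**Figure D2:**
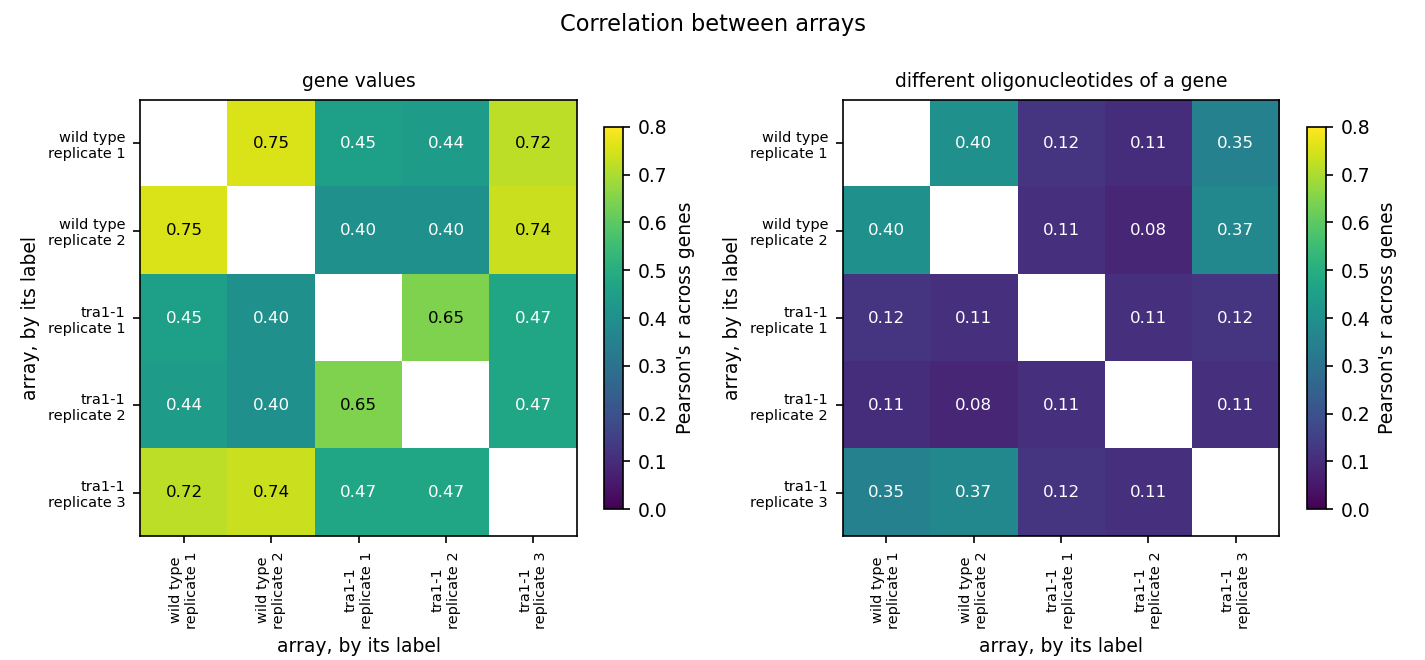
Pearson's r across genes for each pair of the 5 arrays, named by label on both axes, with gene values on the left and with different oligonucleotides of the same gene on the right; the colour scale runs from 0 to 0.8. The 3 pairs among the arrays labelled wild type 1, wild type 2 and tra1-1 replicate 3 reached 0.72 to 0.75 on the left and 0.35 to 0.40 on the right, and the other pairs reached at most 0.65 and 0.12.

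The first comparison asked which transcripts differ between tra1-1 and wild-type cells. In limma, 0 of 4907 genes differed between the arrays labelled tra1-1 and wild type at an adjusted p under 0.05, and the smallest adjusted p was 0.379. At an unadjusted p under 0.05 there were 349 genes, 176 higher and 173 lower on the arrays labelled tra1-1. The genes with the smallest p included alr2, which encodes an alanine racemase, at -2.07 ± 0.30 (SD, n = 2) on the arrays labelled wild type and -0.42 ± 0.62 (SD, n = 3) on those labelled tra1-1. Its difference was 1.65 with a standard error of 0.30 (limma adjusted p = 0.379). SPOM_SPAC977.04, which has no common name, had the smallest p, with a difference of 0.92 ± 0.15 (SE) and ratios of 0.32 to 0.44 on the arrays labelled tra1-1. The neighbours SPOM_SPAC11D3.01C and SPOM_SPAC11D3.02C differed by 1.07 ± 0.20 and 0.96 ± 0.25 (SE). Further higher values that did not pass the test were those of the flavohaemoglobin gene yhb1 (1.20), SPOM_SPCP20C8.02C (0.83), the Hsp70 exchange factor gene fes1 (0.73), the mevalonate kinase gene erg12 (0.66), SPOM_SPBC215.11C (0.64), the ribonuclease gene eri1 (0.63), SPOM_SPAC186.04C (0.61) and pro2 (0.60), all on the same side in every array.

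On the lower side of the same comparison, zym1, which encodes a metallothionein, stood at 2.30 ± 0.38 (SD, n = 2) on the arrays labelled wild type and 0.79 ± 0.54 (SD, n = 3) on those labelled tra1-1. That difference was -1.50 with a standard error of 0.29 (limma adjusted p = 0.379). rgs1, a regulator of pheromone signalling, differed by -1.24 ± 0.30 (SE), and wtf20, of the wtf spore killer family, by -0.83 ± 0.16 (SE). Other values were those of the kinase gene psk1 (-0.83), mil1 (-0.75), tms1 (-0.71), the sorting nexin gene mvp1 (-0.67), the phosphatase subunit gene par1 (-0.64), the Elongator gene elp2 (-0.62), SPOM_SPBC18H10.18C (-0.61), stb3 (-0.59) and the Dicer gene dcr1 (-0.58). None of these 12 passed the test. Differences of at least 2-fold with every array on the same side occurred in 16 genes, 8 higher and 8 lower (5 and 10 with the values as deposited). On both arrays labelled wild type, 75 genes were at least 2-fold from 0, and 64 of these were so on the array labelled tra1-1 replicate 3 with the same sign. Values of the groups did not overlap in 1144 genes (23.3%), and chance gives 20% for 3 arrays against 2. Without the array labelled tra1-1 replicate 3, limma called 205 genes, 121 higher and 84 lower, and without the arrays labelled tra1-1 replicates 1 and 2 it called 1, mcp3, with a single array on that side that was assumed to vary like the wild-type-labelled pair.

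Since the series title names Wee1, wee1 was examined together with other regulators of entry into mitosis. wee1 had ratios of 0.66 and 0.09 on the arrays labelled wild type and -0.11, -0.13 and -0.07 on those labelled tra1-1. Its difference was -0.48 with a standard error of 0.19, which did not pass the test (limma adjusted p = 0.685). Without the array labelled wild type 1 it was -0.19 and without that labelled wild type 2 it was -0.76. The wee1 oligonucleotides disagreed, with differences of -0.82 and -0.13 when tested apart. mik1, the kinase that shares the Cdc2 site with Wee1, stood at -1.06 and -1.39 on the arrays labelled wild type, and at -0.13, -0.12 and -1.31 on those labelled tra1-1, low on the same arrays as tra1 (difference 0.70 ± 0.32, SE, limma adjusted p = 0.704). The phosphatase genes cdc25 and pyp3, both acting on Cdc2, differed by -0.02 and -0.41, and the polo kinase gene plo1 by 0.36. Differences of cdc2, the cyclin gene cdc13 and the Wee1-inhibiting kinase genes cdr1 and cdr2 were 0.19, 0.09, -0.10 and -0.02. The checkpoint kinase genes chk1 and rad3 differed by -0.13 and 0.08, and tra2 by -0.27. The marker genes ura4, leu1 and ade6 differed by 0.02, 0.30 and 0.20. None of these passed the test, and 0 of the 20 members of the G2/M list passed when adjusted over the list alone. That list had a median difference of 0.00, with 10 members higher and 10 lower.

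Gene lists showed small shifts between the labelled groups, and camera at its preset correlation called 8 lists, 7 of which are described. All 8 calls were lost with an estimated correlation (adjusted p = 0.529 with an estimated correlation for each), and fry called 0 lists. The calls below rest on the preset correlation. All 8 lists kept their direction with an estimated correlation and with fry, and 6 of 8 kept it without the arrays labelled tra1-1 replicates 1 and 2. Genes of amino acid synthesis were higher on the arrays labelled tra1-1, with a median difference of 0.17 over 58 genes and 46 of them above 0 (camera adjusted p = 2.57e-05), as in pro2 (0.60) and arg5 (0.61). Targets of the G1/S factor MBF (median 0.23, 16 of 21 above 0, camera adjusted p = 0.00962) included ssb1 (0.55) and mrc1 (0.48). Cytosolic ribosomal protein genes (median 0.08, 91 of 124 above 0, camera adjusted p = 0.00349) and genes of purine and pyrimidine synthesis (median 0.13, 17 of 20 above 0, camera adjusted p = 0.0108) were also higher, for example rpp202 (0.58), ade8 (0.58) and ade2 (0.38), although rpl3703 was lower (-0.51). M cell specific genes were lower (median -0.43, 8 of 8 below 0, camera adjusted p = 0.000581), as in the pheromone receptor and transporter genes mam2 (-0.87) and mam1 (-0.57). The lists of mating and early sexual differentiation (median -0.29, 15 of 20 below 0, camera adjusted p = 0.00227), with ste4 (-1.04) and rgs1 (-1.24), and of glycolysis and fermentation (median -0.13, 14 of 20 below 0, camera adjusted p = 0.0192), with ght5 (-1.78) and pdc201 (-0.68), were lower too. No member of any list passed the gene test over all genes. The MBF median was 0.07, 0.13 and 0.38 without the arrays labelled tra1-1 replicates 1, 2 and 3, and the M cell median -0.26 without that labelled wild type 1. The medians of ribosomal proteins and of purine and pyrimidine synthesis were 0.13 and 0.20 without that labelled tra1-1 replicate 3, and that of amino acid synthesis 0.11 without that labelled tra1-1 replicate 2. On the array labelled tra1-1 replicate 3, where tra1 was low, these lists lay near the arrays labelled wild type. Amino acid synthesis had medians of -0.27 and -0.24 on the arrays labelled wild type 1 and 2 and 0.01, 0.00 and -0.26 on those labelled tra1-1 replicates 1, 2 and 3. In the same order, ribosomal proteins had 0.03, -0.01, 0.14, 0.18 and -0.02, purine and pyrimidine synthesis -0.05, -0.12, 0.15, 0.24 and -0.08, and glycolysis 0.31, 0.40, 0.04, 0.07 and 0.32. The other called lists are given by array below.

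The other 22 lists were not called, with camera adjusted p from 0.0578 to 0.93. Median differences were -0.11 for the SAGA complex, to which Tra1 belongs, -0.04 for NuA4, 0.01 for DNA damage checkpoint and repair, 0.16 for Forkhead targets and 0.10 for histones. Stress lists stood at -0.13 (core stress response) and 0.07 (heat shock proteins and chaperones), P cell specific genes at -0.03, and meiosis and sporulation at 0.00. Nutrient lists stood at 0.01 for nitrogen starvation, 0.01 for glucose-repressed genes, 0.06 for phosphate response and -0.01 for iron acquisition. Sterol synthesis, flocculation and cell wall synthesis had 0.08, 0.15 and -0.01. Ribosome biogenesis, oxidative phosphorylation and the proteasome had 0.08, -0.02 and 0.05, heterochromatin and silencing 0.00 and strain markers 0.16. Adjusted over the list alone, 1 phosphate gene was higher, and 2 core stress genes and 1 mating gene were lower. Means and medians differed in sign for nitrogen starvation, glucose-repressed genes, meiosis and the G2/M list, where the order of the groups is not settled.

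**Figure D3:**
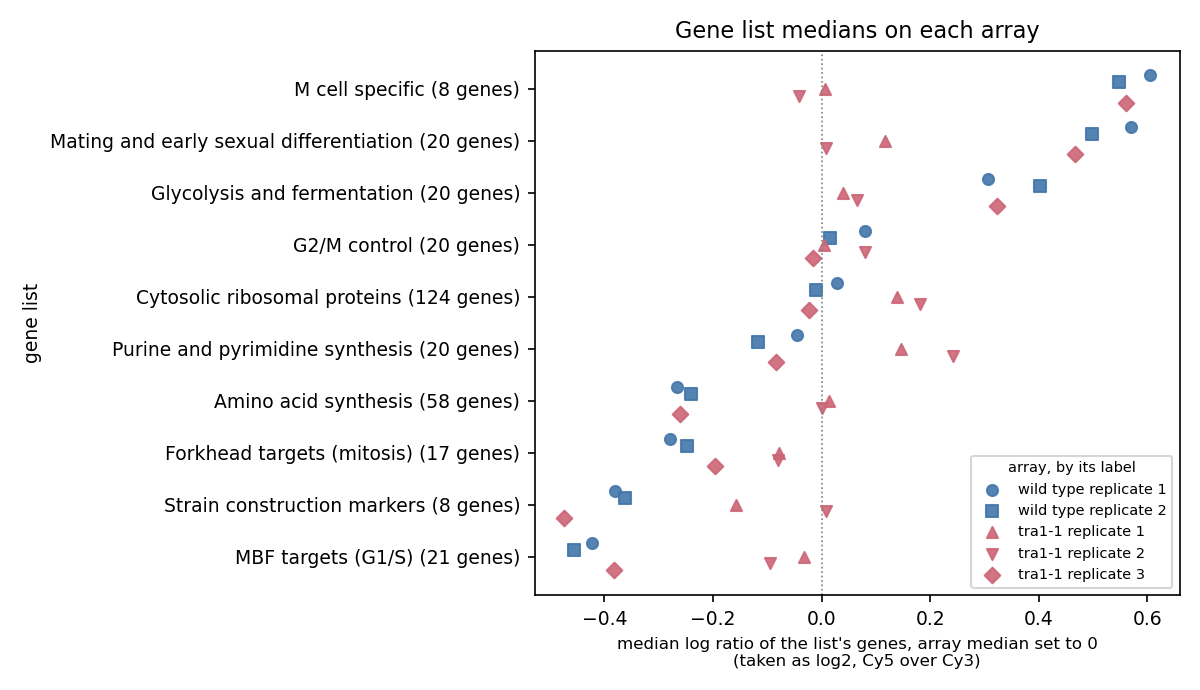
Median log ratio (x axis, taken as log2 of Cy5 over Cy3, array median set to 0) of the genes of each called list described here and of the G2/M list (y axis) on each array, blue for arrays labelled wild type and red for arrays labelled tra1-1. The M cell list stood at 0.61, 0.55 and 0.56 on the arrays labelled wild type 1, wild type 2 and tra1-1 replicate 3 and at 0.01 and -0.04 on those labelled tra1-1 replicates 1 and 2.

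Ratios on the arrays labelled wild type were tested against 0, since a self-self array should show only effects of dye and spot. Of 4907 genes, 559 passed limma's test, 314 above and 245 below 0. High and low below assume Cy5 over Cy3 and would swap, with every sign, if the ratio were turned. Among the highest were gpd3, which encodes a glyceraldehyde-3-phosphate dehydrogenase, at 3.39 ± 0.12 (SD, n = 2, limma adjusted p = 0.00926), SPOM_SPAC27D7.11C at 2.96 and the small heat shock protein gene hsp9 at 2.90 ± 0.19 (SD, n = 2, limma adjusted p = 0.00703). The hexose transporter gene ght5 stood at 2.22, and genes of sexual differentiation stood high: the M-factor precursor gene mfm2 at 2.06, rgs1 at 2.02, the transcription factor gene ste11 at 1.83 and the meiotic regulator gene mei2 at 1.56. The galactose genes gal10 and gal7 were at 1.37 and 1.28, whereas gal1 stood at -0.12 and -0.27 on the 2 arrays. SPOM_SPBPB10D8.01 and SPOM_SPBPB10D8.02C were lowest at -2.94 and -2.78, and other low genes included obr1 (-2.10), alr2 (-2.07), the telomeric helicase gene tlh1 (-2.04), hsp16 (-1.81), met17 (-1.77), tra1 (-1.72), gst2 (-1.65) and the glutaredoxin gene grx4 (-1.52), all past the test. tlh1 has near-identical copies, which the probes were not checked to tell apart. On the array labelled tra1-1 replicate 3, gpd3, hsp9 and ste11 stood at 3.58, 2.70 and 1.99, and on those labelled tra1-1 replicates 1 and 2 none of these 3 genes exceeded 0.56. With the values as deposited, limma called 1561 genes, 95 above and 1466 below 0, since the median of all genes then lay at -0.30. Leaving out either array labelled wild type left a lone array there, whose spread was taken from the arrays labelled tra1-1, so its calls are not given. Without the array labelled tra1-1 replicate 3, 1367 genes passed.

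On the arrays labelled wild type camera called 8 lists, 3 above and 5 below the other genes, 7 of which are described. All 8 calls were lost with an estimated correlation (adjusted p = 0.668 to 0.669 with an estimated correlation), and fry called 0 lists. Lists of mating and early sexual differentiation (median 0.46, 8 of 20 genes above 0 past the test, camera adjusted p = 0.000641), M cell specific genes (median 0.60, 4 of 8, camera adjusted p = 0.000947) and glycolysis and fermentation (median 0.36, 8 of 20, camera adjusted p = 0.00177) were above the other genes. Amino acid synthesis (median -0.28, 7 of 58 below 0 past the test and 2 above, camera adjusted p = 3.18e-05) and MBF targets (median -0.52, 8 of 21 below and 1 above, camera adjusted p = 0.000914) were below them. So were Forkhead targets (median -0.25, 0 of 17 past the test, camera adjusted p = 0.00265) and strain markers (median -0.30, 1 of 8, camera adjusted p = 0.00934). The strain markers leu1, his3, his7, lys1 and arg3 are also members of the amino acid list. The others, ura4, ade6 and ade1, belong to the purine and pyrimidine list, so this call is not separate from those lists. MBF targets had medians of -0.42 and -0.46 on the arrays labelled wild type 1 and 2, -0.38 on that labelled tra1-1 replicate 3, and -0.03 and -0.10 on those labelled tra1-1 replicates 1 and 2. The mating list had 0.57, 0.50 and 0.47 on the former arrays and 0.12 and 0.01 on the latter. The tra1 ratio was low on the same arrays.

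Ratios on the arrays labelled tra1-1 were tested against 0 as the direct reading of mutant over wild type, which keeps any dye effect. limma called 384 of 4907 genes, 275 above and 109 below 0. The mitochondrial genes mrps16 and tim8, the oligosaccharyltransferase gene ost4 and SPOM_SPAP27G11.16 stood at 1.45 ± 0.34, 1.20 ± 0.01, 1.35 ± 0.25 and 1.31 ± 0.24 (SD, n = 3). The same genes stood at 1.37, 1.18, 1.32 and 1.25 on the arrays labelled wild type, and their differences between the groups were 0.08, 0.02, 0.03 and 0.07. Not all of the highest were so alike. SPOM_SPCC794.04C stood at 1.43 and 2.10 in the groups labelled tra1-1 and wild type, a difference of -0.67. Differences were 0.40 for the unnamed probe pair c212_100009, 0.24 for fic1 and 0.08 for SPOM_SPCC320.03. urg3, a uracil-regulated gene, stood at -0.70 and -0.44 in the groups labelled tra1-1 and wild type. Of the 384 genes, 193 also passed on the arrays labelled wild type with the same sign, and 0 had the opposite sign. Independent lists would share 23.0, but these lists were not independent by design, so no conclusion is drawn from the excess. All arrays shared the dye order and the oligonucleotides, and the array labelled tra1-1 replicate 3 resembled those labelled wild type. tra1 (-0.72 ± 1.29, SD, n = 3), mik1 (-0.52) and wee1 (-0.10) did not pass, with limma adjusted p of 0.25, 0.164 and 0.516. camera called 0 of 30 lists, the lowest adjusted p being 0.156, for ribosomal proteins. With the values as deposited, 2613 genes were called, 66 above and 2547 below 0, the median of all genes then being -0.37. The count was 1100 without the array labelled tra1-1 replicate 3, and 140 and 65 without those labelled tra1-1 replicates 1 and 2.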

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

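Leaving out tra1-1 replicates 1 and 2 together, the ratio fits over other sets of arrays and the list tests against 0 under other methods were chosen after the data were seen, and the other alternatives before. The count of 0 genes between the labelled groups was also 0 with the values as deposited, quantile normalization, other handling of missing values, probes taken singly and a robust prior. It was 2 with scale normalization (alr2 and zym1), 95 with array weights, 329 with the replicate block and 1 (mcp3) without the arrays labelled tra1-1 replicates 1 and 2. The ratio against 0 gave 384. It ranged from 0 to 205 when an array was left out, with 205 without that labelled tra1-1 replicate 3. Only 2 replicate numbers were shared between the groups, and deviations of same-numbered arrays from their group means correlated at 0.04 and -0.03. Deviations of the 2 arrays labelled wild type mirror each other, and those of the arrays labelled tra1-1 carry their split. These correlations therefore cannot decide whether the numbers pair the arrays. The array labelled tra1-1 replicate 3 was alone in its block, so the block removed it from the comparison, and all 205 genes called without it were among the 329. Array weights gave it 0.375 against 1.16 to 1.48 for the others, and all 95 genes were among the 205. The count of 2-fold genes was 32 with scale normalization, 47 with probes taken singly and 10 without the arrays labelled tra1-1 replicates 1 and 2, and it ran from 12 to 76 when an array was left out (76 without tra1-1 replicate 3, 29 and 32 without wild type 1 and 2). wee1 stayed below 0 under every alternative run. The group difference of its mean ran from -0.76 without wild type 2 to -0.19 without wild type 1. Its oligonucleotides taken singly gave -0.82 and -0.13, and the ratio against 0, another quantity, gave -0.10. It did not pass in any of these, with limma adjusted p from 0.0815 to 0.996. The 8 lists became 0 with an estimated correlation, with fry, with the ratio against 0 and without the arrays labelled tra1-1 replicates 1 and 2, and 3 to 12 when an array was left out (5, 3 and 12 without tra1-1 replicates 1, 2 and 3).

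Calls on the ratios labelled tra1-1 against 0 numbered 2613 as deposited, 627 with quantile normalization, 672 with scale normalization and 733 in the fit over all 5 arrays, and 65 to 1100 with an array left out (1100 without tra1-1 replicate 3, 140 and 65 without replicates 1 and 2). Those on the ratios labelled wild type numbered 1561 as deposited and 856 with scale normalization. They numbered 395, 428 and 1367 without tra1-1 replicates 1, 2 and 3. Calls without wild type 1 or 2, which leave a lone array in that group, are not given. The 8 lists on the latter became 0 with an estimated correlation and 0 with fry.

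Several genes changed sign without passing the test. ura4 became -0.0305 with the replicate block, -0.0265 as deposited and -0.00480 with array weights. With an array left out, cdc25 ran from -0.177 to 0.136, cdc13 ran from -0.0357 to 0.222, cdr1 ran from -0.331 to 0.121, cdr2 ran from -0.088 to 0.0223 and ura4 ran from -0.087 to 0.138. Without the arrays labelled tra1-1 replicates 1 and 2, tra1 became -0.49, mik1 -0.0863, cdc13 -0.012, cdr1 0.37 and cdr2 0.10. The ratio against 0 is another quantity than the group difference. It had the opposite sign for tra1 (-0.72), mik1 (-0.52), cdc13 (-0.0767), ura4 (-0.25), leu1 (-0.14), alr2 (-0.42), SPOM_SPAC11D3.01C (-0.0688), yhb1 (-0.19), SPOM_SPAC11D3.02C (-0.20), ssb1 (-0.30) and mrc1 (-0.0463). It was also opposite for cdc25 (0.17), cdr1 (0.11), cdr2 (0.0638), chk1 (0.21), zym1 (0.79), mil1 (0.081), rgs1 (0.78), psk1 (0.28), ste4 (0.22), mam2 (0.26), mam1 (0.0818), rpl3703 (0.0583), ght5 (0.44), pdc201 (0.17) and pyp3 (0.22), of which only zym1 passed. Where no cause is given, the cause was not tested.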

Other observations

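All tests in this part were chosen after the values were seen. mcp3 stood at 1.06 and 1.06 on the arrays labelled wild type 1 and 2 and at -2.04 on that labelled tra1-1 replicate 3, with 0.26 and -0.18 on the others. It was the 1 gene at least 1 from 0 on both arrays labelled wild type and at least 1 from 0 on the other side on that array, against 64 of 75 genes on the same side there. Its oligonucleotides differed on that array (-0.996 and -3.08), and 1 of them had no value on the array labelled wild type 2. mei4, a transcription factor gene of meiosis, also stood apart there at -1.41, against 0.10 and 0.39 on the arrays labelled wild type. Of the uracil-regulated genes, urg1 and urg2 were low on the arrays labelled wild type (-0.76 and -1.71 for urg1, a mean of -1.73 for urg2) and on that labelled tra1-1 replicate 3 (-1.45 and -1.83). On the arrays labelled tra1-1 replicates 1 and 2 they stood at -0.31 and -0.41 (urg1) and -0.37 and -0.49 (urg2). urg3 did not follow them, with means of -0.44 in the group labelled wild type and -0.70 in that labelled tra1-1.

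The arrays labelled wild type 1 and 2 and tra1-1 replicate 3 shared ratios that the arrays labelled tra1-1 replicates 1 and 2 lacked. A dye effect common to all arrays would show on each of them, since the labels give every array the same dye order. Between different oligonucleotides of a gene, the covariance of the arrays labelled tra1-1 replicates 1 and 2 with those labelled wild type was 0.202 of that between the latter (95% bootstrap interval 0.162 to 0.242), and that of the array labelled tra1-1 replicate 3 was 1.06. A technical batch acting on single oligonucleotides would split half-differences between the oligonucleotides of a gene as it splits half-sums, but the gap in correlation was only 0.100 as large (0.0309 to 0.176). The first value restates the pattern, found as ratios that the arrays labelled tra1-1 replicates 1 and 2 lack, so it is no separate test of a dye effect. It also could not see a dye effect on single oligonucleotides. The second value argues against such a batch as the whole cause of the likeness of the 3 arrays that share ratios. Its gap set pairs among those 3 arrays against pairs across the split. The pair labelled tra1-1 replicates 1 and 2 was left out, so its likeness is not covered. For differences between oligonucleotides that pair had the highest r, 0.575, against at most 0.538 for the other pairs. Nor could the value see a bias acting alike on both oligonucleotides of a gene. The intervals resample genes with the 5 arrays fixed, so they hold no spread between arrays. An exchange of labels remains a candidate explanation and a hypothesis, in which the arrays labelled wild type 1 and 2 would hold tra1-1 RNA and those labelled tra1-1 replicates 1 and 2 wild-type RNA. The lowest correlation between different oligonucleotides among the 3 arrays that share ratios exceeded the highest of the other 7 pairs by 0.237 (0.204 to 0.267) over the 4673 genes with both oligonucleotides measured on every array. tra1 was in the lowest 1% of genes on those 3 arrays and not on the other 2, or in the highest 1% if the ratio were turned. The tra1 values and the likeness of the arrays prompted this hypothesis, so they are no separate evidence for it. Under it the arrays labelled tra1-1 replicates 1 and 2 would be self-self arrays, yet some list medians were shifted there. Ribosomal proteins had 0.14 and 0.18 there, against 0.03, -0.01 and -0.02 on the other arrays. Purine and pyrimidine synthesis had 0.15 and 0.24, against -0.05, -0.12 and -0.08. These shifts were not tested by array. On the arrays labelled wild type, a batch of cultures or RNA would cancel in the ratio if both dyes held a single preparation. It could act there only with different preparations in the 2 dyes, which the labels do not state. Then it cannot be told apart from an exchange of labels, since no dates or batches are given, although tra1 ranked 20 or lower there. Whether the tra1-1 mutation lowers the transcript is not given in the sources used here, which leaves the tra1 part of this test conditional. The labelled split gave 0 genes in limma (349 at an unadjusted p under 0.05) and the highest of the other splits into 3 and 2 gave 224. The 10 splits are too few for a share under 0.05, and none can fall below 0, so the count decides nothing about chance. The split with 224 set the arrays labelled tra1-1 replicates 1 and 2 apart from the rest, which restates the structure of the samples described above.

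Genes near chromosome ends lay farther from 0 than other genes on the arrays that share ratios. The 229 genes within 50 protein-coding genes of an end had a mean distance from 0 of 0.435 and 0.453 on the arrays labelled wild type 1 and 2 and 0.479 on that labelled tra1-1 replicate 3. Other genes had 0.277, 0.266 and 0.329, and 0 of 10000 random sets of 229 genes reached as far on any of these arrays. The random sets drew genes singly, whereas genes near ends lie in runs, and adjacent genes were alike on these arrays. The count of 0 may therefore overstate how rare such distances are. On the arrays labelled tra1-1 replicates 1 and 2 the distances were 0.211 and 0.254 near ends and 0.206 and 0.236 elsewhere, and 3388 and 749 random sets reached as far. The medians of genes near ends were -0.12, -0.17 and -0.19 on the arrays that share ratios, with the opposite sign if the ratio were turned. Noise of single oligonucleotides would lower the correlation between the oligonucleotides of a gene near ends, but it was 0.579 and 0.589 there against 0.387 and 0.378 elsewhere on the arrays labelled wild type. On the arrays labelled tra1-1 replicates 1 and 2 it was 0.170 and 0.206 near ends against 0.121 and 0.101 elsewhere. Oligonucleotides repeated poorly on those 2 arrays, so their distances could hide a difference near ends. An effect of position near an end, where silenced and subtelomeric genes lie, remains a hypothesis. The value of 0.435 includes genes of families with near-identical copies, whose probes could read each other's transcripts, and these were not set apart.

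Adjacent genes were compared to ask whether ratios run along the chromosomes. Over 4482 adjacent pairs, r was 0.0893 and 0.0717 on the arrays labelled wild type 1 and 2 and 0.0583 on that labelled tra1-1 replicate 3, and none of 1000 shuffled orders reached as far. It was -0.0079 and -0.0165 on the arrays labelled tra1-1 replicates 1 and 2, within the shuffled orders. The oligonucleotides of a gene repeated less well on those arrays, and the neighbour r of the array labelled wild type 2, scaled to that, would be 0.0276 and 0.0239 there (lower 95% limits 0.0164 and 0.0142), against a shuffled 95th percentile of 0.0234 and 0.0256. The values therefore leave open whether position makes neighbours alike on those arrays.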
